A study of Mus musculus with 18 samples.

How the data were processed

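RNA was measured in immune cells sorted from the livers of C57BL/6J mice with tumours raised by Ras and Myc oncogenes. The 18 libraries used fall into 6 groups of 3: untreated and treated mice, each with CD45+ cells sorted as CD3+CD8+, CD3+CD8- or CD3-CD8-. Per the labels, libraries were made from total RNA with a low-input RNA kit and the TruSeq v2 kit, and all carry the same batch label. The library names give sequencing lane 2 or 3 and a letter code with a number that may stand for the animal, which the labels do not say; 7 such codes occur, and treated and untreated libraries share none. Replicates are named here by the number alone. The letters of untreated number 6 and of treated number 19 differ from those of the other libraries of their treatment, and whether they mark another experiment is not stated. The title of 1 treated CD3+CD8- library repeats a digit of its number, and it was taken as number 11. Untreated and treated follow the treatment label of each library.

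The deposited table of counts holds whole numbers per gene for 48440 gene identifiers and 40 library columns, of which 18 were used and 22 were not. The authors also deposited FPKM values per gene, with a symbol and a locus for each identifier; these served for symbols, for positions and for 1 alternative. The submitters' processing notes name Trim Galore 0.6.7, HTSeq 0.13.5, Cufflinks 2.2.1 and DESeq2 3.20 without saying what each did. The aligner and the genome build are not given in the sources used here. Symbols came from the FPKM table for 48242 identifiers and from a reference list for 194, while 4 had none; 228 identifiers shared a symbol with another. Of the 48440 identifiers, 47864 were found in GENCODE vM21, a release on build GRCm38; 100% of these had the same chromosome and 90.48% the same start. Positions printed are those of the FPKM table.

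Within each sorted fraction, treated and untreated libraries were compared with edgeR 4.0.16 (R 4.3.3): genes kept by filterByExpr, TMM scaling, and the quasi-likelihood F-test (two-sided) with Benjamini-Hochberg adjustment over the genes tested, called at an adjusted p below 0.05. Differences between fractions in the treatment effect, and CD3+CD8+ against CD3+CD8- cells in untreated mice, were contrasts in an edgeR fit of all 18 libraries as 6 groups. Levels are CPM, the counts per library total after TMM scaling as edgeR computes them, as mean ± SD over 3 libraries. The levels of the sort markers come from the scaling of all 18 libraries, and the levels beside a fold change from the scaling of that fraction's 6, so the same gene can carry a different CPM in each. Library totals are the sums of the count column. A share read as 0 allows up to 3 counts of a library's total, and such limits cover counting error only.

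Gene lists for pathways, T cell states, cell type markers and RNA quality, 46 in all, were written before the data were examined, as were the tests, the libraries in each fit, the rule for naming genes and the first set of alternatives. Each list with at least 5 tested members was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated from the residuals, and fry, which asks whether a list moves on balance 1 way, stand beside it. Counts adjusted over the list alone take the edgeR p-values of the list's members only. Lists describe the mixture of cells in a sorted fraction, not single cells.

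The genes named by rule were, for each comparison of treated with untreated cells, 12 fixed genes (Ptprc, Cd3e, Cd8a, Cd8b1, Cd4, Pdcd1, Cd274, Isg15, Gzmb, Ifng, Mki67 and Tcf7). To these were added the 5 largest changes each way among called genes with a mean log2 CPM of at least 3 and no overlap between groups or, where none was called, the 5 of smallest unadjusted p. Last came up to 3 members of each list that camera called or that had at least 3 called members. For a difference between fractions they were the 5 genes of smallest adjusted p with a mean log2 CPM of at least 3; for the T cell fractions, the sort markers and the 5 largest changes each way. Unnamed gene models and antigen receptor segments were left out of these picks and counted as groups. A gene named outside the rule was chosen after its values were seen, and the text says so.

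Alternatives chosen beforehand were DESeq2 size factors, library totals alone, no filter (at least 1 count), a stricter filter (CPM of at least 5 in at least 3 libraries), DESeq2 1.42.0 in full, limma voom with quality weights, all 18 libraries in 1 fit, the lane as a covariate, removal of 454 immunoglobulin, erythroid, hepatocyte and mitochondrial genes, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, and leaving out each library in turn; for lists, fry and the estimated correlation. For differences between fractions and between the T cell fractions they were also only the libraries compared and a replicate block on the number, fixed or, for differences between fractions, random (limma voom). The FPKM table repeated 67 identifiers. Chosen after seeing the data were a correction for transcript GC content, fits without the 3 libraries with over 50% of their counts on 5 ribosomal loci, fits also without the library labelled untreated CD3+CD8- replicate 6, removal of the ribosomal loci, and a fit of 21683 protein-coding genes. The GC correction fitted, in each library, a smooth curve (span 0.3) of its deviation from the mean over transcript GC content in genes with a mean log2 CPM of at least 3; that curve entered the edgeR fit as an offset. GC content was known for 48058 identifiers.

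The pipeline was tested on simulated counts with the depths and the spread of these libraries and changes planted in 50 genes per fold. Each gene was drawn independently, so differences that many genes of a library share, such as its cell mixture, were absent apart from GC trends where named. The counts of false calls hold for that setting only. In CD3+CD8+ cells 4% of genes changed 2-fold, 44% of those changed 4-fold and 70% of those changed 8-fold were found, with 4 false calls among 10309 genes. In CD3+CD8- cells these shares were 4%, 52% and 84%, and in CD3-CD8- cells 18%, 68% and 94%, with 7 false calls in each. With the GC trends of the CD3-CD8- libraries put into the simulation, the uncorrected fit gave 669 false calls among 13654 genes and the GC-corrected fit gave 4. Of differences between fractions that were 8-fold, 52% to 60% were found.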

Results

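Liver immune cells were sorted from C57BL/6J mice bought at 7 weeks of age whose liver tumours had been raised by injecting Ras and Myc oncogenes into the tail vein under high pressure, a method that carries DNA into hepatocytes. Mice were untreated or received poly(I:C), a synthetic double-stranded RNA that triggers antiviral sensors, at 4 mg/kg together with 200 µg of an antibody against PD-L1, the ligand of the inhibitory receptor PD-1, every other day for 6 doses. The dosing notes also list an antibody against VEGF-A, a growth factor of blood vessels, which the labels of these treated libraries do not name. The series asks how combined immunotherapy shapes the immune cells of these livers. RNA was sequenced from CD45+ cells in 3 sorted fractions, CD3+CD8+, CD3+CD8- and CD3-CD8-, with 3 untreated and 3 treated libraries of each.

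Total counts per library were 4680522, 6703330 and 2400074 in untreated CD3+CD8+ replicates 1, 5 and 18, and 4687180, 3977229 and 19115752 in treated CD3+CD8+ replicates 11, 2 and 19. They were 4455533, 3571164 and 1829155 in untreated CD3+CD8- replicates 5, 18 and 6, and 2990098, 10332742 and 14250972 in treated replicates 11, 2 and 19. In CD3-CD8- cells they were 10361522, 26835919 and 10066700 in untreated replicates 1, 5 and 18, and 4158555, 17421424 and 28233682 in treated replicates 11, 2 and 19. In 3 libraries most counts lay on 5 ribosomal loci: 87.0% in untreated CD3+CD8+ replicate 1, 79.7% in untreated CD3+CD8+ replicate 18 and 84.0% in treated CD3+CD8- replicate 2, which left 606759, 486461 and 1654913 counts on other genes. In the other 15 libraries that share was 0.35% to 2.26%. A count of 0 allowed a level of up to 0.0723 CPM in untreated CD3-CD8- replicate 5 and up to 5.57 CPM in untreated CD3+CD8+ replicate 18, the lowest and highest of these limits over the 18 libraries, which cover counting error only.

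The sort markers separated the T cell fractions, with 1 exception, and T cell transcripts also appeared in the fraction sorted as CD3-CD8-. Cd8a, the CD8 alpha chain, averaged 636 ± 344 CPM (SD, n = 3) in untreated and 1247 ± 148 CPM in treated CD3+CD8+ cells, against 14.7 ± 8.11 CPM in treated CD3+CD8- cells. Cd4, the coreceptor of helper and regulatory T cells, averaged 279 ± 174 CPM in untreated and 775 ± 289 CPM in treated CD3+CD8- cells. The library labelled untreated CD3+CD8- replicate 6 had 641 CPM of Cd8a, where the other untreated libraries of that fraction had 4.65 and 6.82 CPM, and 103 CPM of Cd4, where they had 450 and 285 CPM. In CD3-CD8- cells Cd3e, a chain of the CD3 complex, averaged 96.0 ± 38.8 CPM untreated and 238 ± 69.6 CPM treated, and Cd8a 177 ± 114 and 782 ± 220 CPM. Ms4a1, which encodes the B cell protein CD20, averaged 561 and 507 CPM in untreated and treated CD3-CD8- cells and reached 345 CPM in untreated CD3+CD8+ replicate 18. S100a8, an abundant neutrophil protein, averaged 2613 ± 2548 CPM in untreated and 6483 ± 4561 CPM in treated CD3+CD8- cells, and 7501 CPM in treated CD3-CD8- replicate 11. Xist, an RNA of female cells, ran from 0.563 to 316.3 CPM in untreated and from 0.3974 to 572.6 CPM in treated CD3-CD8- cells. Kdm5d, a gene of the Y chromosome, ran from 0 to 33.7 CPM and from 0 to 44.35 CPM there. Both groups may therefore hold mice of both sexes. Sex was not a term in any fit, and its part in the spread was not tested.

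**Figure D1:**
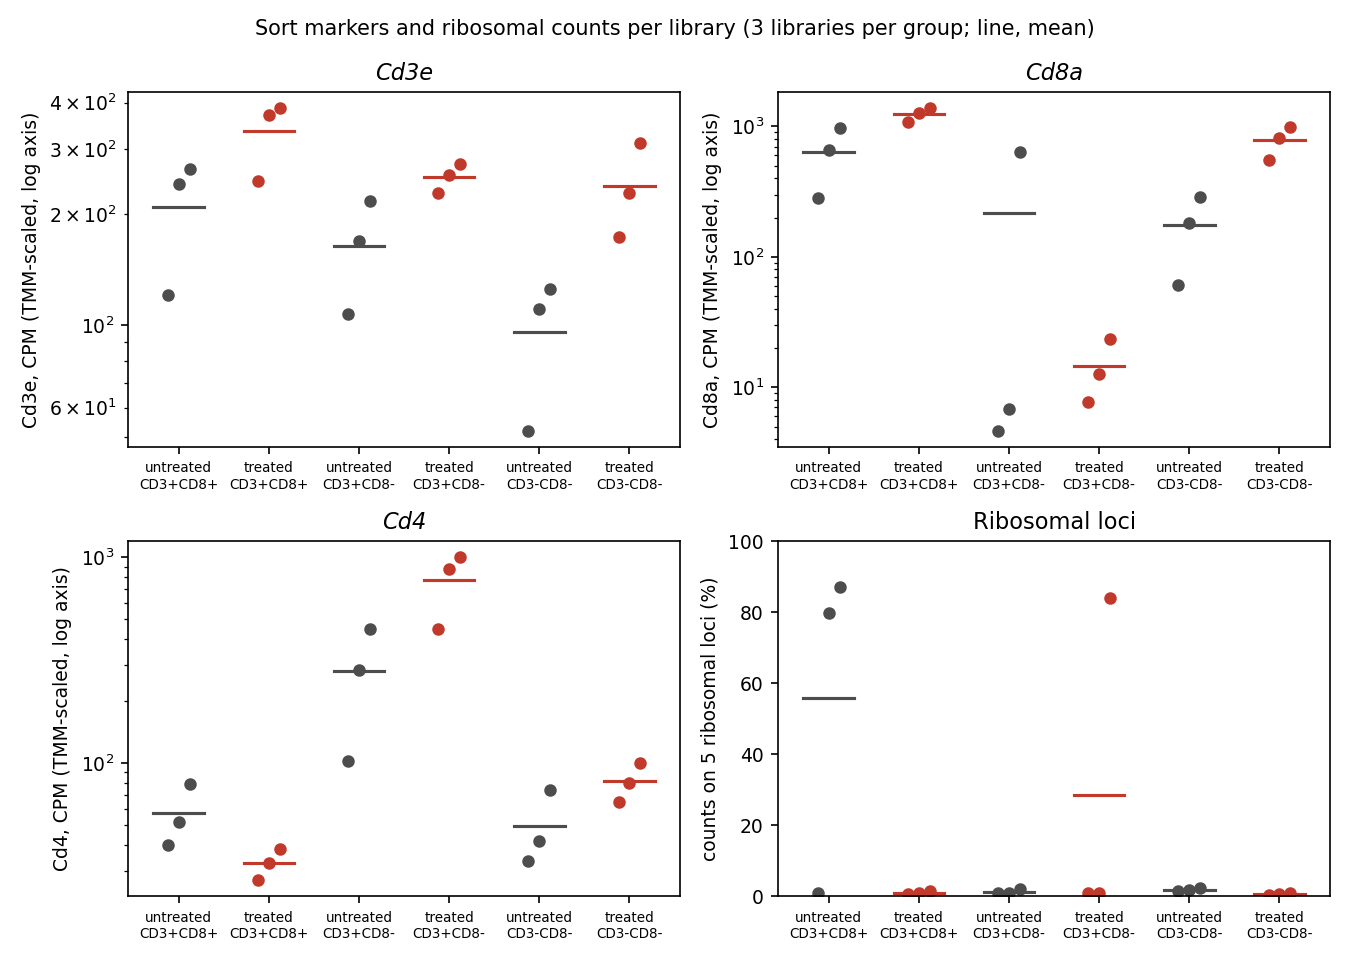
TMM-scaled CPM (log axis) of Cd3e, Cd8a and Cd4, and percent of counts on 5 ribosomal loci, in each of the 18 libraries by treatment (grey untreated, red treated) and fraction; points are libraries and lines are means of 3. Cd8a stood at 641 CPM in the library labelled untreated CD3+CD8- replicate 6, and treated CD3-CD8- libraries averaged 782 CPM.

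In CD3+CD8+ cells from treated mice, 21 of 24 genes of inhibitory receptors and exhaustion had higher mean levels than in those from untreated mice, although no single gene passed the test. Havcr2, which encodes the inhibitory receptor TIM-3 (ENSMUSG00000020399.14, chromosome 11, 46454935 to 46481255), averaged 78.2 ± 24.4 CPM (SD, n = 3) treated and 18.9 ± 2.58 CPM untreated. Tox, a transcription factor of exhausted T cells (ENSMUSG00000041272.11, chromosome 4, 6686353 to 6991557), averaged 189.8 ± 18.6 and 42.7 ± 19.6 CPM. Gzmb, which encodes granzyme B, averaged 791.5 ± 176 and 201.2 ± 44.2 CPM. Fasl, a death ligand of killer cells, averaged 107.4 ± 5.23 and 37.3 ± 5.87 CPM. In the edgeR fit their log2 fold changes were 2.03 (SE 0.34), 2.10 (SE 0.36), 1.97 (SE 0.38) and 1.52 (SE 0.27), each at a Benjamini-Hochberg adjusted p of 0.273.

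Of the 24 tested genes of inhibitory receptors and exhaustion, 21 had a positive log2 fold change in CD3+CD8+ cells, with a median of 1.46; none passed over all genes tested, and 17, all up, passed when adjusted over the list alone. Camera called this list up at an adjusted p of 1.89e-32, with adjusted p = 0.0579 with an estimated correlation. Pdcd1, which encodes PD-1, averaged 128.9 ± 48.4 CPM treated and 35.0 ± 33.4 CPM untreated (log2 1.76, SE 0.59). Prdm1, a regulator of effector differentiation, stood at 1.68 (SE 0.30) on the log2 scale. Of 24 cytotoxic effector genes 16 were positive with a median of 0.69; 5 passed up and 1 down adjusted over the list alone, and adjusted p = 0.293 with an estimated correlation. Gzma, which encodes granzyme A, averaged 1751 ± 642 and 380.3 ± 183 CPM. Of 21 genes of naive and central memory T cells 2 were positive, the median was -0.58 and 0 passed adjusted over the list alone (adjusted p = 0.324 with an estimated correlation); Satb1 and Lef1, transcription factors of resting T cells, stood at -1.06 (SE 0.34) and -0.86 (SE 0.32). All 8 CD8 T cell markers were positive with a median of 0.64 and 0 passed adjusted over the list alone (adjusted p = 0.383 with an estimated correlation), Cd8a at 0.92 (SE 0.47), Cd8b1 at 0.34 (SE 0.55) and Cd3e at 0.63 (SE 0.36). Tcf7 stood at -0.55 (SE 0.42), Mki67 at 0.15 (SE 0.54), Ifng at 0.38 (SE 0.42), Cd274 at -0.19 (SE 0.32), Cd4 at -0.83 (SE 0.34) and Ptprc at 0.15 (SE 0.46).

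B cell, MHC class II and plasmacytoid dendritic cell transcripts had lower mean levels in treated than in untreated CD3+CD8+ cells, and the untreated libraries differed widely. Of 13 B cell markers 0 were positive, with a median of -2.41; 12 passed down adjusted over the list alone, and adjusted p = 0.324 with an estimated correlation. Ighd, the delta heavy chain of naive B cells, averaged 5.43 ± 0.80 CPM treated and 132.2 ± 190 CPM untreated. After the GC correction the mean log2 CPM of the B cell markers ran from 1.95 to 6.92 in untreated libraries (4.34 ± 2.49) and was 1.96 ± 0.21 in treated ones. The median log2 fold change was -0.97 without untreated replicate 18. It was -0.12 without the libraries rich in ribosomal counts, untreated replicates 1 and 18 here. Of 14 genes of MHC class II antigen presentation the median was -2.07, with 7 down adjusted over the list alone (adjusted p = 0.324 with an estimated correlation). It was -0.87 without replicate 18 and -0.60 without both. Of 19 plasmacytoid dendritic cell markers 2 were positive, the median was -1.0 and 9 passed down adjusted over the list alone (adjusted p = 0.0791 with an estimated correlation); Klk1 averaged 13.7 ± 2.65 and 43.7 ± 8.31 CPM. Cd209a, a lectin of dendritic cells, averaged 2.02 ± 0.43 and 13.5 ± 1.56 CPM. Of 46 type I interferon-stimulated genes 14 were positive, with a median of -0.15 and 0 passing adjusted over the list alone (adjusted p = 0.543 with an estimated correlation), and Isg15 stood at -0.28 (SE 0.53). Of 84 cytosolic ribosomal proteins 6 were positive, with a median of -0.47 and 0 passing adjusted over the list alone (adjusted p = 0.692 with an estimated correlation). The median was 0.19 without untreated replicate 5. Without the libraries rich in ribosomal counts the medians of neutrophil and Kupffer cell markers turned from -0.98 and -2.13 to 1.65 and 1.08.

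By edgeR, 0 of 10654 genes in CD3+CD8+ cells passed, with 624 at an unadjusted p under 0.05. No overlap between groups was seen for 1059 genes, 9.94%, where chance gives 10%. DESeq2 called 220 genes (58 up, 162 down) and limma voom with quality weights 197 (86 up, 111 down), while edgeR without untreated replicate 5 called 180. Camera called 22 of 41 lists (7 up, 15 down) and none held with an estimated correlation; untreated replicates 1 and 18 were both rich in ribosomal counts.

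**Figure D2:**
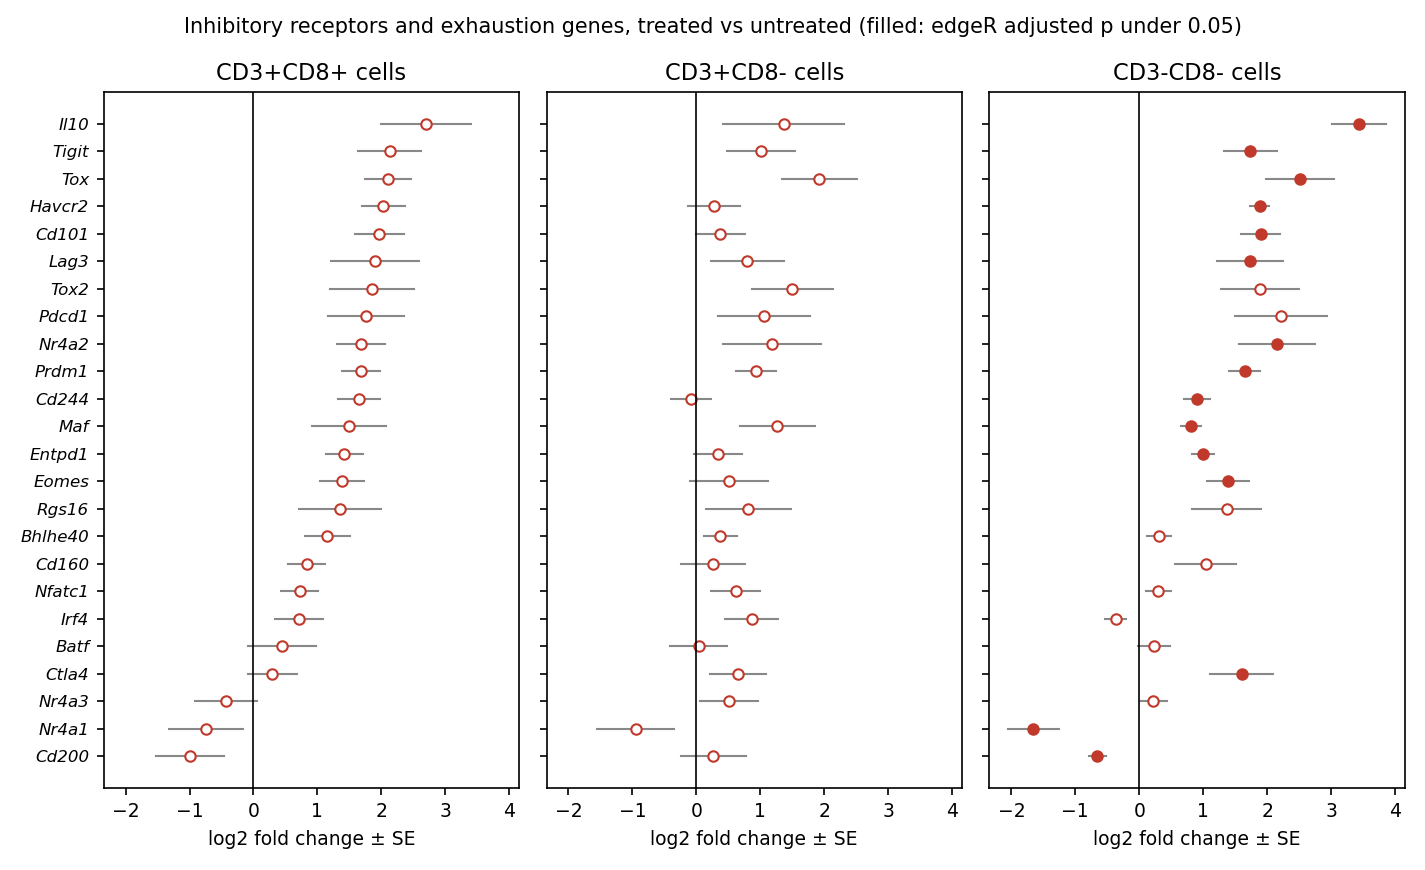
The log2 fold change, treated over untreated, of each tested gene of inhibitory receptors and exhaustion in the 3 sorted fractions, with bars of 1 SE from edgeR and filled points for an adjusted p under 0.05. The medians were 1.46 in CD3+CD8+, 0.63 in CD3+CD8- and 1.38 in CD3-CD8- cells, and no difference between fractions passed its own test.

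In CD3+CD8- cells, which hold helper and regulatory T cells, no gene passed the test between treated and untreated mice. The highest list medians were those of follicular helper T cell, exhaustion and neutrophil genes. Cd4 averaged 800.9 ± 290 CPM (SD, n = 3) treated and 291.9 ± 185 CPM untreated (log2 1.46, SE 0.56). Il21, a cytokine of follicular helper T cells, averaged 89.0 ± 127 and 7.73 ± 8.85 CPM. Ly6g, a neutrophil surface protein, averaged 62.3 ± 36.1 and 15.1 ± 5.67 CPM (log2 2.06, SE 0.47).

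Of 24 genes of inhibitory receptors and exhaustion in CD3+CD8- cells, 22 were positive with a median of 0.63, and 0 passed adjusted over the list alone (adjusted p = 0.426 with an estimated correlation). Tox stood at 1.93 (SE 0.59), Prdm1 at 0.93 (SE 0.32) and Pdcd1 at 1.06 (SE 0.72). Of 11 genes of follicular helper T cells 9 were positive with a median of 0.77 (adjusted p = 0.459 with an estimated correlation), and of 14 regulatory T cell genes 10 were positive with a median of 0.47 (adjusted p = 0.459 with an estimated correlation), and 0 of either list passed adjusted over the list alone; Nrp1, a regulatory T cell surface protein, stood at 1.25 (SE 0.54). Of 22 neutrophil markers 16 were positive with a median of 0.61, and 1 passed up adjusted over the list alone (adjusted p = 0.426 with an estimated correlation); Ngp, a granule protein, stood at 2.10 (SE 0.65). Of 15 NK cell markers 3 were positive with a median of -0.85, and 4 passed down adjusted over the list alone (adjusted p = 0.426 with an estimated correlation); Klrk1, which encodes the receptor NKG2D, averaged 84.4 ± 27.2 CPM treated and 205.8 ± 90.7 CPM untreated. Of 47 type I interferon-stimulated genes 10 were positive with a median of -0.26 and 0 passing adjusted over the list alone (adjusted p = 0.540 with an estimated correlation), and a median of 0.02 without untreated replicate 18; Irf7 stood at -0.68 (SE 0.27), Mx1 at -0.69 (SE 0.29) and Isg15 at -0.59 (SE 0.45). Of 84 cytosolic ribosomal proteins 3 were positive with a median of -0.73 and 0 passing adjusted over the list alone (adjusted p = 0.762 with an estimated correlation), and the median was 0.14 without untreated replicate 6; Rpl36 averaged 3.27 ± 2.31 and 142.4 ± 237 CPM. Cd8a stood at -3.96 (SE 1.60) and Cd8b1 at -3.48 (SE 1.24), with untreated replicate 6 the library that held them. Gzmb stood at -1.11 (SE 0.54), Ifng at 0.46 (SE 0.37), Mki67 at 0.04 (SE 0.34), Tcf7 at -0.40 (SE 0.37) and Cd274 at -0.17 (SE 0.31).

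The genes of smallest unadjusted p in CD3+CD8- cells were Abca13 (log2 2.51, SE 0.53), Ly6g, Samd3 (-1.34, SE 0.34), Nanos1 (1.96, SE 0.52) and Wfdc21 (1.45, SE 0.40), none of which passed. By edgeR 0 of 11197 genes passed, with 198 at an unadjusted p under 0.05 and a smallest Benjamini-Hochberg adjusted p of 0.9998; 460 genes, 4.11%, did not overlap, where chance gives 10%. DESeq2 called 4 genes (3 up, 1 down) and limma voom with quality weights 0. Camera called 19 of 43 lists (8 up, 11 down), and none held with an estimated correlation.

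In CD3-CD8- cells all 8 CD8 T cell markers and 13 of 24 genes of inhibitory receptors and exhaustion rose with treatment, and 16 of 19 B cell markers and 10 of 15 genes of MHC class II antigen presentation fell. Fewer passed over all genes tested after correction for transcript GC content. The medians of these 4 lists kept their direction, and no list held with an estimated correlation. Havcr2 rose from 30.6 ± 3.00 to 113.1 ± 12.7 CPM (SD, n = 3), a log2 fold change of 1.89 (SE 0.15). Il10, an anti-inflammatory cytokine (ENSMUSG00000016529.5, chromosome 1, 131019845 to 131024974), rose from 1.69 ± 0.58 to 18.8 ± 9.04 CPM (log2 3.44, SE 0.42). Timd4, a receptor of resident Kupffer cells, fell from 12.4 ± 8.83 to 0.37 ± 0.23 CPM (log2 -4.85, SE 0.70). Ciita, the master regulator of MHC class II genes, fell from 161.9 ± 24.9 to 56.4 ± 4.70 CPM (log2 -1.52, SE 0.16). Their Benjamini-Hochberg adjusted p-values in edgeR were 0.00720, 0.00826, 0.00905 and 0.00732, and all 4 also passed after that correction.

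All 8 CD8 T cell markers rose in CD3-CD8- cells with a median log2 of 1.57, all 8 also adjusted over the list alone (adjusted p = 0.840 with an estimated correlation). Cd3g, a chain of the CD3 complex, rose from 393.4 ± 181 to 1970 ± 379 CPM and Cd8a from 233.9 ± 146 to 1034 ± 321 CPM; Cd8b1 rose by 1.68 (SE 0.50) and Cd3e by 1.30 (SE 0.35). After the GC correction the median was 1.62. Over all genes tested 1 of the 8, Cd3g, then passed, and all 8 did adjusted over the list alone. T cell receptor segments rose in 28 of 73 tested, with 0 falling and a median of 1.30. Of 24 genes of inhibitory receptors and exhaustion 13 rose and 2 fell, with a median of 1.38 and 16 up and 2 down adjusted over the list alone (adjusted p = 0.840 with an estimated correlation). The GC-corrected median was 1.30, and 8 up and 1 down passed, with 18 up and 2 down adjusted over the list alone. Prdm1 rose by 1.65 (SE 0.25), while Pdcd1 averaged 275.2 ± 59.1 and 58.7 ± 60.2 CPM and did not pass (edgeR adjusted p 0.0563). Of 25 cytotoxic effector genes 6 rose and 3 fell, with a median of 0.17, adjusted p = 0.921 with an estimated correlation and 6 up and 3 down adjusted over the list alone; after the GC correction 3 rose, 0 fell and the median was -0.06. Among these, Gzma rose from 1235 ± 268 to 4224 ± 624 CPM and Gzmb from 587.3 ± 256 to 1904 ± 296 CPM, both also after the GC correction. Eomes, a transcription factor of memory and killer lymphocytes, rose by 1.38 (SE 0.33), while Klrb1c, which encodes NK1.1, fell by 1.31 on the log2 scale (SE 0.36), a call that the GC correction ended (log2 -1.489, SE 0.382, edgeR adjusted p 0.0704). Of 22 naive and central memory T cell genes 11 fell and 1 rose, with a median of -0.84. Adjusted over the list alone 12 were down and 1 up (adjusted p = 0.488 with an estimated correlation). After the GC correction the median was -0.74 and 5 fell and 0 rose, with 13 down and 1 up adjusted over the list alone. Tcf7 fell from 92.6 ± 17.3 to 37.9 ± 4.61 CPM and Satb1 by 1.02 on the log2 scale (SE 0.17). Klf2, in this list, had -1.13 (SE 0.18), which turned to 0.087 with the GC correction.

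Of 19 B cell markers 16 fell and 0 rose in CD3-CD8- cells, with a median of -1.04 and 17 down adjusted over the list alone (adjusted p = 0.921 with an estimated correlation). After the GC correction the median was -0.93 and 6 fell, with 18 down adjusted over the list alone. Fcer2a, which encodes the IgE receptor CD23 of mature B cells, fell from 282.4 ± 77.6 to 96.0 ± 20.8 CPM. Ly6d fell from 290.7 ± 77.6 to 52.4 ± 6.43 CPM. Cd79a, a chain of the B cell receptor, fell from 433.6 ± 105 to 151.3 ± 34.9 CPM, and was 1.999-fold lower (SE 0.223 on the log2 scale) after the GC correction, which ended the call (edgeR adjusted p 0.0561). Of 15 genes of MHC class II antigen presentation 10 fell and 1 rose, with a median of -1.24 and 11 down and 1 up adjusted over the list alone (adjusted p = 0.840 with an estimated correlation). With GC content corrected the median was -0.90 and 3 fell, with 12 down and 0 up adjusted over the list alone. Of 18 Kupffer cell markers 7 fell, with a median of -1.30 and 8 down adjusted over the list alone (adjusted p = 0.921 with an estimated correlation). Their GC-corrected median was -1.03, and 1 fell, with 4 down adjusted over the list alone. Of 26 genes of tumor-associated macrophages 7 fell and 1, Il10, rose, with a median of -0.96 and 7 down and 1 up adjusted over the list alone (adjusted p = 0.921 with an estimated correlation). With the GC correction the median was -0.93 and 2 fell and 1 rose. Retnla, a product of alternatively activated macrophages, fell from 5.82 ± 1.30 to 0.35 ± 0.31 CPM. Of 21 neutrophil markers 4 rose with a median of 1.37, and 4 adjusted over the list alone (adjusted p = 0.921 with an estimated correlation); their levels rested on treated replicate 11, and after the GC correction the median was 1.07 and 0 passed. Ngp averaged 379.2 ± 563 CPM treated and 3.95 ± 1.94 CPM untreated.

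Of 47 type I interferon-stimulated genes 9 rose and 6 fell in CD3-CD8- cells, with a median of 0.12 and 11 up and 10 down adjusted over the list alone (adjusted p = 0.931 with an estimated correlation), and after the GC correction the median was 0.02 and 0 passed. Irf7, the interferon-induced transcription factor, fell by 1.22 on the log2 scale (SE 0.13), and stood at -0.653 (SE 0.149) after the GC correction, which ended the call; Isg15 stood at -0.44 (SE 0.34). Irf1, a transcription factor induced by interferon-gamma, rose by 0.72 (SE 0.19), also after the GC correction. Of 85 cytosolic ribosomal proteins 28 fell and 3 rose with a median of -0.37 and 29 down and 3 up adjusted over the list alone (adjusted p = 0.921 with an estimated correlation); after the GC correction 6 fell and 1 rose with a median of -0.17. Rpl36 fell by 5.61 on the log2 scale (SE 0.99), and by 4.37 (SE 0.91) after the correction. Of 20 glycolysis genes 9 fell with a median of -0.41, and 9 down and 2 up adjusted over the list alone (adjusted p = 0.840 with an estimated correlation), and after the GC correction the median was -0.10 and 2 fell and 1 rose. Coch, which encodes the secreted protein cochlin, rose from 0.85 ± 0.35 to 29.2 ± 8.62 CPM. Ifng stood at 0.91 (SE 0.60), Mki67 at 0.51 (SE 0.18), Cd274 at -0.01 (SE 0.21), Cd4 at 0.68 (SE 0.30) and Ptprc at 0.70 (SE 0.24), none of which passed.

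By edgeR 3522 of 13781 genes in CD3-CD8- cells passed, 1407 up and 2115 down, and 6186 genes, 44.9%, did not overlap, where chance gives 10%. DESeq2 called 3913 genes, limma voom with quality weights 6399 and limma on the deposited FPKM 251. EdgeR called 76 with all 18 libraries in 1 fit and 62 when the 3 libraries rich in ribosomal counts, all of other fractions, were left out of that fit. Fold changes followed transcript GC content with a Spearman's rho of -0.63 across genes, which are not independent replicates: with the genes in 5 equal groups by GC content, 827 rose and 23 fell in the lowest group, and 19 rose and 1329 fell in the highest. With the GC correction 554 genes passed (262 up, 292 down), 441 of them among the 3522, and 3272 of the 3522 kept their sign. Without untreated replicate 5, treated replicate 2 or treated replicate 19 the uncorrected count was 239, 910 or 1185, and the corrected count was 29, 0 or 0; the corrected count was also 0 without untreated replicate 1, 150 without treated replicate 11 and 321 without untreated replicate 18. Camera called 15 of 45 lists (4 up, 11 down), and none held with an estimated correlation.

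**Figure D3:**
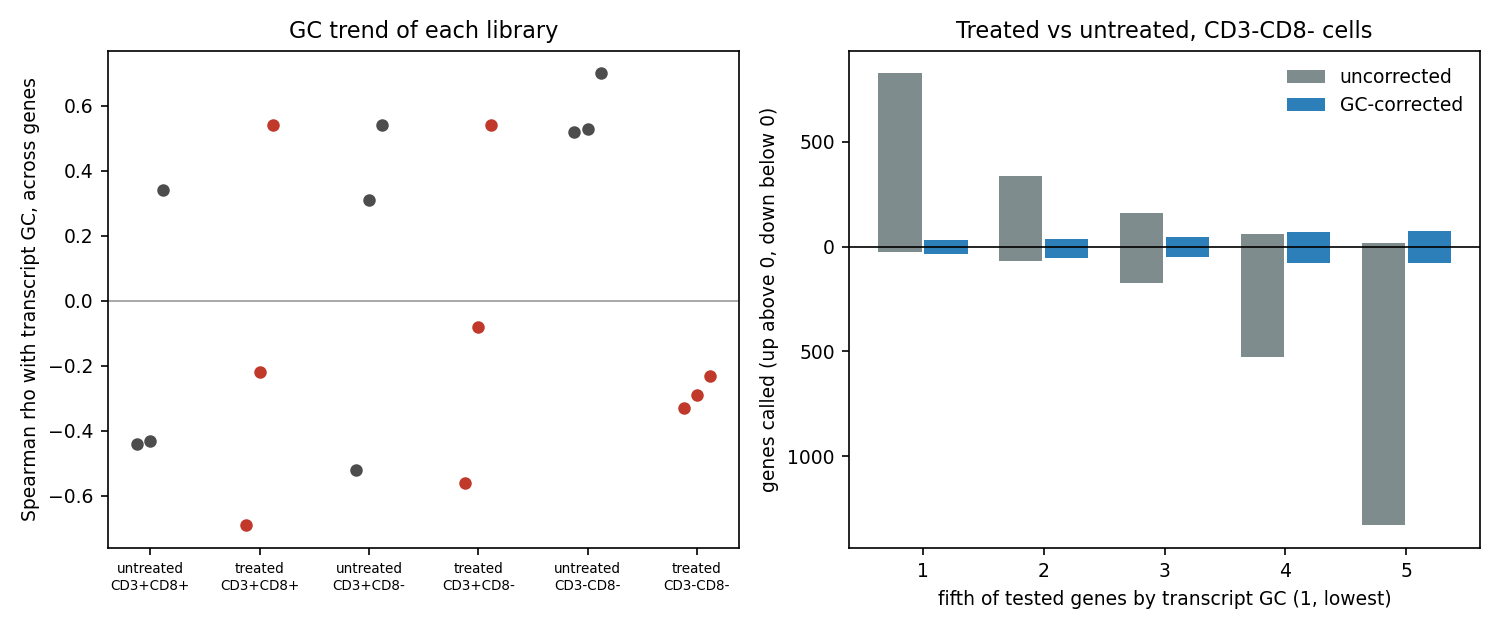
Left, Spearman's rho across genes between each library's deviation from the mean and transcript GC content, by group; right, genes called up (above 0) and down (below 0) in treated against untreated CD3-CD8- cells in 5 equal groups by GC content, before (grey) and after (blue) the GC correction. Before it 827 genes rose in the lowest group and 1329 fell in the highest, and after it 32 and 77 did.

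Whether treatment acted differently between fractions was tested directly, and no gene passed. The treatment effect on Gzmb in CD3+CD8- cells minus that in CD3-CD8- cells was -2.80 on the log2 scale (SE 0.66), and that on Mx1, an interferon-induced antiviral GTPase, was -1.63 (SE 0.32). The effect on Ltf, a neutrophil granule protein, in CD3+CD8+ cells minus that in CD3-CD8- cells was -6.25 (SE 1.62). Between the T cell fractions the genes of smallest adjusted p were small nucleolar and Cajal body RNAs such as Snora23 (-17.57, SE 3.46) and Snord17 (-19.03, SE 3.88). Without the 3 libraries rich in ribosomal counts, 2 of them untreated CD3+CD8+ and 1 treated CD3+CD8-, both had the opposite sign and 0 genes passed.

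Among lists, the effect on 25 cytotoxic effector genes was higher in CD3+CD8+ than in CD3+CD8- cells by a median of 0.96, with 20 positive (adjusted p = 0.156 with an estimated correlation) and 2 up adjusted over the list alone. The untreated CD3+CD8- cells of this difference, and of that on Gzmb, include replicate 6, at 641 CPM of Cd8a. How much that library adds to the list difference was not tested. By edgeR 0 of 13181 genes passed in each of the 3 differences, with 515, 503 and 478 at an unadjusted p under 0.05 for CD3+CD8+ minus CD3-CD8-, CD3+CD8- minus CD3-CD8- and CD3+CD8+ minus CD3+CD8- cells; DESeq2 called 1, 19 and 136. Without untreated CD3+CD8+ replicate 5 the first and last counts were 2 and 127, and the last was 43 or 79 without treated CD3+CD8- replicate 11 or 19. Camera called 5, 15 and 13 of 45 lists, and none held with an estimated correlation.

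In untreated mice, CD3+CD8+ cells were compared with CD3+CD8- cells to describe the sort. Cd4 was lower in CD3+CD8+ cells, at 57.1 ± 20.3 CPM (SD, n = 3) against 279.2 ± 174 CPM (log2 -2.31, SE 0.48, edgeR Benjamini-Hochberg adjusted p 0.0305). Cd8a at 1.56 (SE 1.16) and Cd8b1 at 1.49 (SE 0.98) did not pass, with replicate 6 of the CD3+CD8- cells at 641 CPM of Cd8a. With a replicate block on the number both passed, though number 6 has no other library, so the block fits it exactly. Neutrophil genes were lower: of 23 neutrophil markers 8 fell with a median of -4.71, and 22 fell adjusted over the list alone (adjusted p = 0.0786 with an estimated correlation). Slfn4, a gene of activated myeloid cells, averaged 5.72 ± 4.76 against 251.8 ± 229 CPM.

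Of 19 B cell markers 5 were higher in CD3+CD8+ cells with a median of 3.63, and 15 adjusted over the list alone (adjusted p = 0.174 with an estimated correlation); Ms4a1 averaged 127.9 ± 189 against 4.40 ± 2.65 CPM, with replicate 18 at 345 CPM. Of 14 regulatory T cell genes 2 were lower with a median of -0.93, and 5 adjusted over the list alone (adjusted p = 0.0665 with an estimated correlation). The largest differences by rule also held Snora23, Snord118, Fcmr and Pax5, up, and Hcar2, Crispld2, Trem3 and Mefv, down, from 10.29 (SE 2.49) for Snora23 to -7.79 (SE 1.34) for Hcar2. With the block on the number Snora23, Snord118, Fcmr, Ms4a1 and Pax5 did not pass. By edgeR 208 of 13181 genes passed, 24 up and 184 down. The count was 0 without CD3+CD8+ replicate 1, 118 without replicate 5 and 314 without replicate 18, and 48, 37 and 374 without CD3+CD8- replicates 5, 18 and 6; Ms4a1, Pax5 and Snora23 changed sign without the libraries rich in ribosomal counts.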

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

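The GC correction, the fits without libraries rich in ribosomal counts, the removal of ribosomal loci and the protein-coding fit were chosen after the results were seen; the other alternatives were not. Depth limits the untreated CD3+CD8+ cells most, where replicates 1 and 18 kept 606759 and 486461 counts outside the ribosomal loci. Where leaving out libraries leaves 1 in a group, that library is assumed to vary like the others. No paired comparison of treated with untreated libraries was possible because they share no number. Library totals alone moved the median log2 fold change of all genes to 1.17 in CD3+CD8+, -0.53 in CD3+CD8- and -0.17 in CD3-CD8- cells, so counts under that setting are relative to those shifts. Among named genes in CD3-CD8- cells, 1522 values under alternatives kept direction and side of the threshold, 553 kept direction only, 16 gained a call, 1 called gene turned and 10 values of Cd274, which did not pass, changed sign. In CD3+CD8+ cells, where no gene passed, 1276 values kept both, 93 gained a call and 97 changed sign. In CD3+CD8- cells these were 1248, 28 and 28. Unless a cause is given, the cause was not tested.

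Counts of genes called for treated against untreated CD3+CD8+, CD3+CD8- and CD3-CD8- cells, 0, 0 and 3522, became 5, 7 and 2045 with library totals alone, 220, 4 and 3913 with DESeq2, 197, 0 and 6399 with limma voom, 276, 82 and 251 with FPKM, and 15, 0 and 76 with all 18 libraries fitted together. Without a filter they were 380, 195 and 3381. With the GC correction they were 0, 0 and 554. The 3 libraries rich in ribosomal counts were left out of the fit of all libraries together. CD3+CD8- and CD3-CD8- cells then gave 0 and 62, to be set beside the 0 and 76 of that fit. Also without untreated CD3+CD8- number 6 they gave 0 and 256. In CD3+CD8+ cells 1 untreated library was left, so no count is given. Leaving out 1 library at a time gave 0 to 180 in CD3+CD8+ cells (180 without untreated replicate 5), 0 in CD3+CD8- cells and 239 to 3183 in CD3-CD8- cells. The GC-corrected count in CD3-CD8- cells ran from 0 (without untreated replicate 1 or treated replicate 2 or 19) to 321 (without untreated replicate 18), and was 86 with all 18 libraries. DESeq2 size factors, the stricter filter, the lane and the removal of immunoglobulin and similar genes left these counts within 1.5 times.

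Differences between fractions gave 171, 160 and 384 genes without a filter and 1, 19 and 136 with DESeq2, for CD3+CD8+ minus CD3-CD8-, CD3+CD8- minus CD3-CD8- and CD3+CD8+ minus CD3+CD8- cells. Leaving out 1 library gave 0 to 2, 0, and 0 to 127, the highest without untreated CD3+CD8+ replicate 5. With a replicate block on the number all 3 counts stayed 0, also with the GC correction.

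For CD3+CD8+ against CD3+CD8- cells in untreated mice, 208 genes became 775 without a filter, 96 with the lane, 502 with DESeq2, 0 with only the 6 libraries compared, 16 without the libraries rich in ribosomal counts and 688 also without number 6; leaving out 1 library gave 0 to 374. The labels do not say that a number marks an animal. Of 16 pairs with the same number 14 correlated above 0.1 after group means were removed, with a median of 0.348. Of 119 pairs from different groups with different numbers 33 did, with a median of -0.066 and a highest value of 0.499. The higher median is a hint from the data that libraries of the same number share an animal. A replicate block on that number gave 435 genes, and 562 with the GC correction. In both, Cd8a and Cd8b1 passed, Snora23, Snord118, Fcmr, Ms4a1 and Pax5 did not, and Ptprc, which did not pass, changed sign; number 6 has 1 library, which the block fits exactly. Without the libraries rich in ribosomal counts, and then also without number 6, Snora23 turned to -2.18 and -2.27, Ms4a1 to -0.43 and -0.48 and Pax5 to -0.42 and -0.36; Snord118 turned to -0.43 in the latter. In CD3-CD8- cells Klf2 turned to 0.087 with the GC correction.

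Counts of lists called in CD3+CD8+, CD3+CD8- and CD3-CD8- cells, 22, 19 and 15, became 0, 0 and 0 with an estimated correlation and 2, 0 and 3 with fry; with the GC correction these were 1, 0 and 0, and 3, 0 and 1. The list that passed then was inhibitory receptors and exhaustion in CD3+CD8+ cells, at an adjusted p of 0.0215. Without a filter 25 lists were called in CD3-CD8- cells. With all 18 libraries 12 were called in CD3+CD8- cells, and leaving out 1 library gave 12 to 20, 12 without treated replicate 19. Without the libraries rich in ribosomal counts, and then also without number 6, 11 and 11 were called in CD3+CD8+ cells.

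List medians that turned in CD3+CD8+ cells without those libraries, and then also without number 6, were MHC class I at -0.10 and -0.11, Th1 at -0.05 and -0.05, CD4 T cell markers at -0.25 and -0.26, plasma cells at 0.14 and 0.13, neutrophils at 1.65 and 1.65, Kupffer cells at 1.08 and 1.08, conventional dendritic cells 1 at 0.19 and 0.19, endothelial transcripts at 0.63 and 0.63, and mitochondrial genes at 1.11 and 1.10. Endothelial transcripts also turned to 0.26 with all 18 libraries, and mitochondrial genes to 0.15 with the lane. In CD3+CD8- cells, cell cycle genes turned to 0.03 and 0.31 and oxidative phosphorylation genes to 0.04 and 0.38 in these settings; without number 6 cytotoxic genes turned to 0.04, plasma cells to -0.01, erythroid transcripts to 0.68 and ribosomal proteins to 0.29, and with the lane hepatocyte transcripts turned to -0.15. Leaving out 1 library gave medians from -2.68 to 0.51 for Kupffer cells (turned without untreated replicate 18), -1.22 to 0.13 for endothelial transcripts, -1.06 to 0.63 for mitochondrial genes and -0.72 to 0.19 for ribosomal proteins (without untreated replicate 5) in CD3+CD8+ cells. In CD3+CD8- cells it gave -0.35 to 0.02 for type I interferon-stimulated genes and -0.62 to 0.15 for NKT genes (without untreated replicate 18), -0.69 to 1.63 for hepatocyte transcripts, and, without untreated replicate 6, -0.16 to 0.52 for plasma cells, -1.17 to 0.69 for erythroid transcripts, -0.52 to 0.05 for cell cycle genes, -1.07 to 0.14 for ribosomal proteins and -0.40 to 0.15 for oxidative phosphorylation genes.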

Other observations

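The tests of GC content, of T cell carry-over and of cell shares, and the redrawn labels for differences between fractions, were chosen only after the results were seen; the splits of the samples and the thinning were not. The fit without libraries rich in ribosomal counts was added after those libraries and its gene counts were seen, and its test was set before its value for the list was. Further lists were counted in CD3-CD8- cells, and none of them held with an estimated correlation. Of 16 mature dendritic cell markers 7 fell and 2 rose, with a median log2 fold change of -0.88 and 9 down and 2 up adjusted over the list alone (camera adjusted p = 0.840 with an estimated correlation), and after the GC correction the median was -0.67 and 3 fell and 1 rose; Fscn1, an actin-bundling protein of migrating dendritic cells, fell from 10.4 ± 2.49 to 1.57 ± 0.62 CPM (SD, n = 3), with a log2 fold change of -2.864 (SE 0.354) before the correction and -1.736 (SE 0.339) after. Of 44 cell cycle genes 9 fell, with a median of -0.59 and 9 down adjusted over the list alone (adjusted p = 0.921 with an estimated correlation), among them Uhrf1 and Tk1, at 4.49 ± 1.10 and 3.92 ± 1.21 CPM treated against 15.5 ± 2.36 and 12.8 ± 1.04 CPM untreated; after the GC correction the median was -0.38 and 2 fell. Of 22 immediate-early and dissociation response genes 8 fell with a median of -0.96, and 9 adjusted over the list alone (adjusted p = 0.921 with an estimated correlation), and after the GC correction the median was -0.43 and 0 passed. Of 17 genes of the TGF-beta and VEGF axis 2 rose and 2 fell with a median of -0.29 and 2 up and 2 down adjusted over the list alone (adjusted p = 0.921 with an estimated correlation); Tgfb1 fell from 60.4 ± 4.30 to 26.5 ± 3.12 CPM, also after the GC correction, when the median was -0.24 and 1 fell and 0 rose. Of 17 NK cell markers 2 rose and 2 fell with a median of -0.39 and 2 up and 2 down adjusted over the list alone (adjusted p = 0.932 with an estimated correlation), and of 14 regulatory T cell genes 5 rose and 4 fell with a median of 0.07 and 6 up and 5 down adjusted over the list alone (adjusted p = 0.921 with an estimated correlation); after the GC correction the medians were -0.67 and 0.50, and 2 and 1 of these rose and 0 fell. Of 7 platelet and megakaryocyte transcripts 3 fell with a median of -1.72, and 4 adjusted over the list alone (adjusted p = 0.921 with an estimated correlation), with a median of -1.47 and 0 passing after the GC correction, and of 30 hepatocyte transcripts 0 passed (adjusted p = 0.966).

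Of 10632 genes tested in both CD3-CD8- and CD3+CD8+ cells 62.2% had fold changes of the same sign, and of 11152 tested in both CD3-CD8- and CD3+CD8- cells 68.2% did. Of the genes called in CD3-CD8- cells, a set picked for its change there, these shares were 75.3% of 2957 and 84.5% of 3085. Fold changes in CD3+CD8- cells also followed GC content (Spearman's rho -0.36 across genes) and libraries of the fractions share numbers; the share expected without a common effect of treatment was not estimated. Il21 rose from 0.71 ± 0.49 to 17.4 ± 14.2 CPM in CD3-CD8- cells (log2 4.37, SE 0.82), and stood at 3.762 (SE 0.859) after the GC correction, where it did not pass (edgeR adjusted p 0.0571). Immunoglobulin segments fell in 14 and rose in 1 of 197 tested.

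The 3522 genes called in CD3-CD8- cells followed transcript GC content. Of them 91.2% moved in the direction that their side of the median GC content predicts, which restates that trend and is no separate evidence. A shift of the libraries along GC content may account for part of the 3522, and how large a part was not settled. With these GC trends put into the simulation, the uncorrected fit gave 669 false calls among 13654 genes. Untreated CD3-CD8- libraries correlated with GC content across genes at a Spearman's rho of 0.52, 0.53 and 0.70 and treated ones at -0.33, -0.29 and -0.23. Depth is argued against: with every library thinned to 4158555 counts, 2916 genes were still called, 2697 of them among the 3522. GC content as the whole cause is argued against for 4 lists with at least 50% of their genes called in 1 direction: after the correction the median log2 fold change was 1.30 for exhaustion genes (1.38 before), 1.18 for CD4 T cell markers (1.21), -0.74 for naive and central memory T cell genes (-0.84) and -0.93 for B cell markers (-1.04), and the corrected scores of treated and untreated libraries did not overlap. Of the CD4 T cell markers 1 passed after the correction, and Cd4 itself, at 0.916 (SE 0.327), did not. In CD3+CD8+ cells 8 of 10 of these markers were positive after the correction, so a rise of this list is not particular to CD4 T cells. MHC class II genes kept 73%, -0.90 against -1.24, under the 75% asked for, so the test as set did not decide. Their corrected scores still did not overlap, at 7.24 to 7.84 untreated and 6.36 to 6.97 treated, and 14 of 15 genes were negative. These values argue against GC content as the whole cause for this list, though it may have added to the size. The CD8 T cell markers are taken up below. For the genes outside these lists as a group, GC content as the whole cause cannot be told apart from an effect of treatment. After the correction 554 genes passed, and 0 did so without untreated replicate 1 or treated replicate 2 or 19, where fewer libraries also weaken the test. A biological change of cell mixture with treatment stays open, as does a difference in library preparation between the groups other than along GC content.

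T cell transcripts rose in treated cells of a gate that excludes CD3 and CD8. Carry-over of T cells like those of the treated CD3+CD8+ gate is argued against: Tcf7 in treated CD3-CD8- cells stood at 0.13 of its level in treated CD3+CD8+ cells (0.10 to 0.19 over pairs of libraries), below the ranges of the other T cell transcripts compared except Lef1, at 0.12 (0.06 to 0.18): from Cd8b1 at 0.49 (0.28 to 0.90) and Cd8a at 0.67 (0.43 to 0.96) to Cd3g at 1.03 (0.80 to 1.41). A lower share of B cells alone is argued against as well, since CD8 T cell markers minus NK cell markers rose by 2.11 on the log2 scale (-0.23 to 1.15 untreated, 1.87 to 3.40 treated). GC content as the whole cause is argued against by the median of the CD8 T cell markers, 1.62 after the correction and 1.57 before. The calls of 7 of the 8 genes ended as the adjusted p over all genes tested passed 0.05. Cd8a stood at 2.14 (SE 0.51) before and 1.97 (SE 0.53) after. Adjusted over the list alone all 8 still passed. What stays open is a population of Tcf7-low T cells with little surface CD3 and CD8, brought by treatment or by the gate, which may be tested by staining.

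Genes of inhibitory receptors and exhaustion stood higher in treated CD3+CD8+ cells. Fold changes in these cells held no trend on GC content to correct (Spearman's rho -0.01 across genes), so the correction itself decides nothing. GC content is argued against by the size of the libraries' own GC trends at the genes of the list: their median difference between the groups was 0.05, and the highest treated library stood 0.09 above the lowest untreated one, against a median log2 fold change of 1.46. Without the libraries rich in ribosomal counts it was 1.03, but 1 untreated library was then left, so these libraries cannot be told apart from the treatment as part of the size. A lower share of CD8 T cells in the untreated libraries could also contribute: the list minus the CD8 T cell markers differed by 0.54, with untreated libraries at -4.30, -4.63 and -3.63 and treated ones at -3.46, -3.83 and -3.65, which overlap. An effect of treatment on CD8 T cells stays open beside both.

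Other splits of the same samples were counted for each result. For 3 libraries against 3 there are 10 splits, too few for a share under 0.1. In CD3-CD8- cells the real split called 3522 genes, and 554 with the GC correction, where the highest other split called 0 in each case; 1 of 10 splits, the real one, gave as many. In CD3+CD8+ cells the real split called 0 and the highest other 0, and in CD3+CD8- cells these were 0 and 4; every split reaches a count of 0, so that 10 of 10 gave as many says nothing. For lists, the real splits called 22, 19 and 15 in CD3+CD8+, CD3+CD8- and CD3-CD8- cells, the highest others called 24, 25 and 30, and 3, 5 and 9 of the 10 splits gave as many. For CD3+CD8+ against CD3+CD8- cells the real split called 208 genes and another called 283, so 2 of 10 gave as many; the latter exchanged untreated CD3+CD8+ replicate 18 with the library labelled CD3+CD8- replicate 6. For the 3 differences between fractions the real count was 0, so that 50 of 50 redraws gave as many says nothing either; the highest others were 1151, 1 and 91. The 1151 came from 1 redraw, and 91, 68 and 62 from 3 others. The redraw with 1151 kept the real labels in CD3-CD8- cells, but so did others that called 0 for the same difference. What gave these counts was not tested.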
